A study of Mus musculus with 4 samples.

How the data were processed

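Chromatin immunoprecipitation with sequencing was available for 4 libraries, 1 in each of 4 groups: H3K4me3, H3K27me3 and H3K9me3 in mouse embryonic fibroblasts (MEF), and H3K9me3 in secondary MEF. Per the labels, sonicated chromatin had a mean length of 500 bp, libraries were amplified over 18 PCR cycles and size-selected on a gel between 150 and 350 bp, and both H3K9me3 libraries used the same antibody lot. The 3 MEF libraries came from a single flow cell and the secondary MEF library from another. Input libraries were not used here.

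The deposited values are other than a measured level: signed genome positions of aligned reads, with a minus sign for the minus strand and no normalisation. Per the file headers, the authors aligned reads to mouse build mm8 with Bowtie and the options -e 70, -k 2, -m 2, -n 2, -l 36, --best and --concise; the version was not given. Reads with 1 location and reads with 2 locations are listed apart, the latter at both locations. Reads with more locations were left out by the alignment, so repeated sequence is poorly covered. No removal of repeated reads was stated.

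Reads with 1 location were counted in 5 kb bins on chromosomes 1 to 19, X and Y after a shift of 75 bp from the 5' end, with a read length of 36 bases assumed. Read positions on the mitochondrial chromosome were left out. The libraries held 12244976, 9783343, 8912579 and 7986294 such reads, in the order given above, or a mean of 24.7, 19.8, 18.0 and 16.1 reads in each of 494868 bins with a read in any library. Of these reads 91.4%, 93.8%, 98.0% and 97.8% were at distinct positions.

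Thresholds and alternatives were chosen before the data were examined, except where a text says otherwise. A bin was called when its reads were at least 2-fold the library's own mean with a Benjamini-Hochberg adjusted one-sided Poisson value under 0.001. Adjacent called bins were joined into regions. Overlaps were set beside the product of both counts divided by the number of bins. The H3K9me3 libraries were compared in bins with at least 20 reads in both together, scaled by total reads, and a bin differed at 2-fold or more with a Clopper-Pearson interval, allowing 0.1% error, that excluded 1. The same count was made after random binomial reassignment of the pooled reads, drawn 20 times. Correlations were taken across bins on log2(RPM + 0.1), where RPM is the read count scaled by total reads. Other intervals are at the 95% level, Poisson for a fold and Clopper-Pearson for a ratio. A count of 0 was given a floor of 3 reads.

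Chromosome ratios, the ratio along mark levels, positions high in all 4 libraries and the ranking of regions on one read per position were added after seeing the data. Chromosome ratios used 419379 bins called for neither H3K4me3 nor H3K27me3 in MEF. For bins called in both H3K9me3 libraries, the chromosome 12 ratio that a uniform gain predicts was taken from other autosomes with the secondary read threshold lowered by that gain. Bins that differed between the H3K9me3 libraries were matched to compared bins with the same or nearest read counts in MEF (lower bins) or secondary MEF (higher bins).

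Named regions followed a rule: the 10 with the highest bin per library, the 10 bins with the highest smaller fold for H3K4me3 with H3K27me3, and the 10 largest ratios in each direction for the H3K9me3 pair. Regions named for their length, 1 Mb windows, regions above the other marks and bins named after leaving out those high in all 4 libraries lie outside that rule and were chosen after seeing the data. Promoter counts, gene lists and gene names were planned but not run, because a gene annotation on mm8 was not used here.

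The rules were tested on simulated data with 200 altered bins. Within a library, the background was flat and set below the library's mean, while altered bins were set by fold over that mean. Against the simulated mean used for the call they stood higher than their nominal fold. Nominal 3-fold bins were recovered in 97% to 100% of cases and nominal 2-fold bins in 26% (MEF H3K9me3) to 66.5% (MEF H3K4me3). Recovery at 2-fold over the mean used for the call, or over an uneven background, was not simulated. Between the H3K9me3 libraries, a 2-fold change was recovered in 14% of bins when higher and 19% when lower, a 3-fold change in 56.5% and 53.5%, and a 5-fold change in 89.5% and 87.5%, with 153 to 178 other calls among 321554 bins.

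Alternatives covered bin width, one read per position, stricter thresholds, the background of the other marks, a neighbouring bin counted as shared, thinning to equal depth, scaling, minimum reads, the pseudocount and autosomes only. Two-location reads at a weight of 0.5, scaling each chromosome to its own reads, leaving out bins high in all 4 libraries and leaving out chromosomes 12, X and Y were added after seeing the data, as were all alternatives of the overlaps of H3K27me3 with other MEF marks and of the chromosome ratios, and the background of the other marks for shared bins. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.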

Results

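Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map histone H3 methylation marks in mouse embryonic fibroblasts (MEF), connective tissue cells grown from mouse embryos. In MEF, 3 marks were profiled: H3K4me3, which marks active and poised promoters, H3K27me3, which is laid down by Polycomb repressive complex 2, and H3K9me3, which marks heterochromatin. H3K9me3 was also profiled in secondary MEF. These fibroblasts came from chimeric embryos at 13.5 days post coitum that had been made from induced pluripotent stem cells, and they carry doxycycline-inducible Oct4, Klf4 and Sox2. Cells of the injected line were selected with 2 µg/ml puromycin for 48 hours. Each of the 4 groups held 1 library, so no difference below has a replicate check, and every comparison is between libraries and not between conditions. Reads with a single location in the genome numbered 12244976 for MEF H3K4me3, 9783343 for MEF H3K27me3, 8912579 for MEF H3K9me3 and 7986294 for secondary MEF H3K9me3. Levels are given as fold over a library's own mean in 5 kb bins of mouse build mm8, and a bin was called at 2-fold or more with a Benjamini-Hochberg adjusted Poisson value under 0.001. Intervals cover counting error only and are at the 95% level, except those of the bin-by-bin and region-by-region comparison of the H3K9me3 libraries, which allow 0.1% error. Gene annotation on this build was not used here, so regions are named by position.

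H3K4me3 in MEF was concentrated in few and high regions. Of 494868 bins that held a read in any library, 31010 (6.27%) were called, and they held 61.6% of the library's reads. The median called bin stood at 4.89-fold, and 67.4% of the 20193 regions were a single bin wide. Among the 10 regions with the highest bins, chromosome 5 from 143220001 to 143235000 reached 92.4-fold (95% interval 88.6 to 96.3). Chromosome 7 reached 77.2-fold (73.8 to 80.7) in the region from 140700001 to 140715000 and 75.9-fold (72.5 to 79.4) in the region from 100780001 to 100810000. In the highest bin of these 3 regions H3K27me3 lay between 2.43-fold and 2.93-fold. The longest H3K4me3 region covered 105 kb of chromosome 8, from 87590001 to 87695000, at a mean of 8.12-fold, with H3K27me3 at a mean of 2.03-fold. The 1 Mb windows with the most bins that exceeded the other MEF marks were on chromosome 19 from 5000001 (67 of 200 bins) and on chromosome 10 from 79000001 (60 of 200 bins).

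H3K27me3 in MEF had long domains beside many short regions. It was called in 55982 bins (11.3%), which held 40.9% of the reads, at a median of 2.78-fold. Of its 21031 regions 53.9% were a single bin wide, while 872 reached 50 kb or more, against 49 for H3K4me3. In 1 kb bins the median region was 1 kb for H3K27me3 and 2 kb for H3K4me3, and the 90th percentile was 4 kb for both. The longest was then 70 kb for H3K27me3 and 54 kb for H3K4me3. With 5 kb bins also held to 2-fold above the mean of the other MEF marks, 234 H3K27me3 regions reached 50 kb, the longest 220 kb. Lengths therefore depend on bin width and background. In 5 kb bins against the library mean, the longest domain covered 470 kb of chromosome 12, from 112525001 to 112995000. It had a mean of 5.08-fold, with H3K4me3 at 0.930-fold. Domains of 455 kb on chromosome 8 (123565001 to 124020000) and 335 kb on chromosome 4 (147480001 to 147815000) had mean levels of 7.20-fold and 6.73-fold. The highest single bins outside positions that were high in all 4 libraries were on chromosome 9 from 62940001 to 62945000, at 40.7-fold (37.9 to 43.6), and on chromosome 2 from 31460001 to 31465000, at 36.5-fold (33.9 to 39.2). In these bins H3K4me3 stood at 4.53-fold and 1.78-fold.

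Strong H3K4me3 and strong H3K27me3 met in the same bins more often than independent placement gives. Among the 15318 called H3K4me3 bins of 5-fold or more, 1470 also carried H3K27me3 at 5-fold or more, against 245 for independent lists of these sizes. A larger part, 9701 bins, had H3K27me3 under 2-fold. At the lower threshold of both calls, 11503 bins were shared against 3508 for independent lists. All 6 pairs of libraries exceeded independence at that threshold, and this pair did so least, by 3.28 times against 3.83 to 5.95 times for the others. Of the 1636 bins with H3K27me3 of 10-fold or more, 1135 had H3K4me3 of at least 2-fold. Both marks together were highest on chromosome 3 from 89405001 to 89410000 (H3K4me3 18.0-fold, H3K27me3 22.6-fold), chromosome 7 from 98710001 to 98715000 (21.5-fold and 17.9-fold), chromosome 1 from 94930001 to 94935000 (24.9-fold and 17.7-fold) and chromosome 14 from 57025001 to 57030000 (17.6-fold and 21.8-fold). These bins were ranked by the smaller fold after leaving out bins high in all 4 libraries, a step chosen after seeing the data, since 8 of the 10 leading bins by the planned rule were of that kind. Among the 5 longest H3K4me3 regions, 90 kb of chromosome 11 from 96085001 to 96175000 carried both marks, at means of 7.79-fold H3K4me3 and 10.7-fold H3K27me3, and it was singled out after its values were seen. A 5 kb bin does not show whether the marks sit on the same nucleosomes or alleles.

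H3K9me3 in MEF was spread thinly, and most of its called bins were also H3K27me3 bins. It was called in 50912 bins (10.3%), which held only 27.5% of the reads, at a median of 2.44-fold. Of these bins 32871 (64.6%) were also called for H3K27me3, against 5759 for independent lists. The longest H3K9me3 region, 235 kb of chromosome 4 from 147590001 to 147825000, overlapped the 335 kb H3K27me3 domain named above, with H3K9me3 at a mean of 3.07-fold and H3K27me3 at 7.19-fold. The next, 230 kb of chromosome 8 from 123600001 to 123830000, lay inside the 455 kb H3K27me3 domain, at 3.61-fold and 7.59-fold. Where H3K27me3 was between 10-fold and 20-fold, the median bin had 4.28-fold H3K9me3, and all 1480 such bins were called for it. In those bins the median of the secondary MEF library was 2.97-fold. H3K4me3 was raised there as well, at a median of 3.11-fold, with 66.9% of the bins called for it. When bins had also to stand 2-fold above the mean of the other MEF marks at the same place, 4879 MEF H3K9me3 bins were left. Their longest region, 70 kb of chromosome 11 from 3030001 to 3100000, was at 5-fold or more in all 4 libraries. The next longest was 35 kb. In 1 kb bins against the library mean the longest MEF H3K9me3 region was 73 kb, so the lengths above depend on bin width and background.

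**Figure D1:**
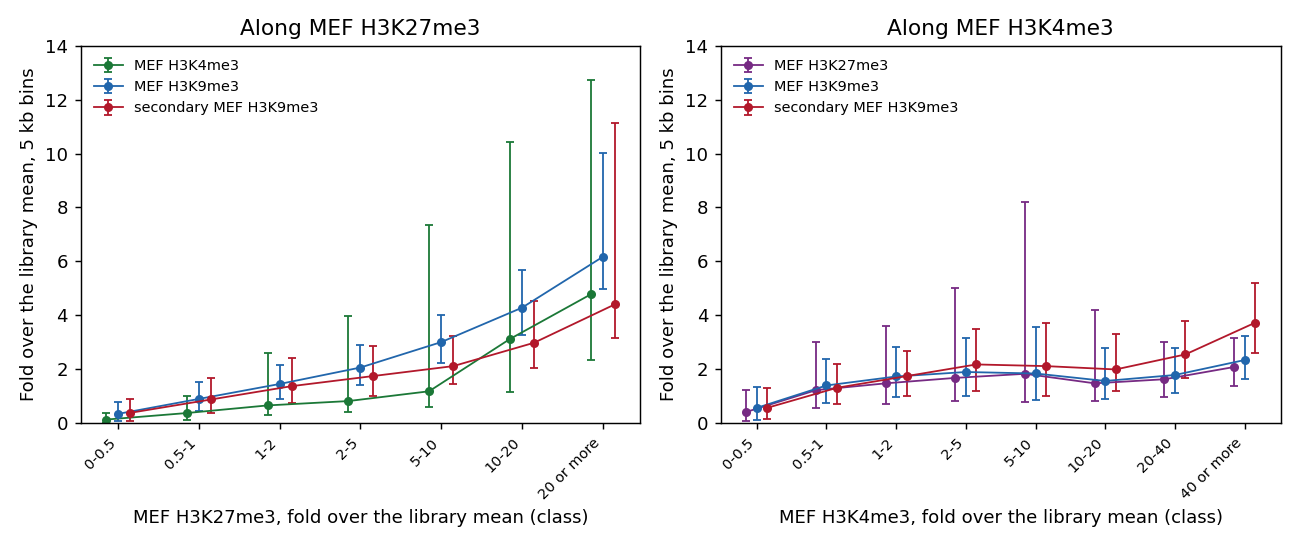
Median fold over the library mean in 5 kb bins (y axis; bars from the 10th to the 90th percentile of bins) for bins sorted into classes of MEF H3K27me3 level (left) or MEF H3K4me3 level (right). Both H3K9me3 libraries rose along H3K27me3, MEF to 4.28-fold and secondary MEF to 2.97-fold in the class from 10 to 20, while at 40-fold H3K4me3 or more the secondary library stood at 3.72-fold and the MEF library at 2.33-fold.

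A smaller set of regions carried H3K9me3 above the other marks in both kinds of fibroblast. By the background of the other marks, 1647 bins were called in both H3K9me3 libraries, a count made after seeing the data. Both lists share the MEF H3K4me3 and H3K27me3 reads as background, which by itself raises their overlap. The bins were spread over 692 windows of 1 Mb, with 192 on chromosome 5, 168 on chromosome 4 and 133 on chromosome 12. The windows with the most were on chromosome 4, with 46 bins from 152000001, 25 from 139000001 and 23 from 151000001, and on chromosome 15, with 22 bins from 87000001. The window on chromosome 4 from 152000001 had a mean of 1.99-fold in MEF and 2.24-fold in secondary MEF, with H3K27me3 at 1.42-fold. In the window from 139000001 these means were 2.17-fold and 2.41-fold, with H3K27me3 at 2.51-fold, so H3K9me3 was below H3K27me3 there on average. Among the regions with the highest bins, chromosome 15 from 76000001 to 76015000 reached 19.9-fold in MEF (17.9 to 22.1) and 28.2-fold in secondary MEF in its highest bin, with H3K4me3 at 3.92-fold and H3K27me3 at 3.14-fold there. On chromosome 4 from 3005001 to 3020000 the highest bin reached 18.2-fold in MEF (16.3 to 20.3) and 24.6-fold in secondary MEF. There H3K4me3 stood at 4.77-fold and H3K27me3 at 4.86-fold, just under the 5-fold level that defines bins high in all 4 libraries. The MEF regions ranked above these on chromosomes 15 and 4 all held bins high in all 4 libraries. Chromosome 5 from 143505001 to 143530000, among the longest MEF regions above the other marks, reached 9.05-fold (7.71 to 10.6) and 16.4-fold.

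Some H3K9me3 regions stood higher in the secondary MEF library than in the MEF library. The longest region above the other marks in the secondary library covered 165 kb of chromosome 5, from 117920001 to 118085000, at a mean of 2.94-fold, with 1.74-fold in MEF. On chromosome 4 from 139385001 to 139510000, 125 kb had means of 3.15-fold in secondary MEF and 2.15-fold in MEF. The highest bin outside positions high in all 4 libraries was on chromosome X from 165330001 to 165335000, at 43.5-fold (40.3 to 46.8) in secondary MEF, with 702 reads there and 144 in MEF. The 15 kb region around it, from 165325001 to 165340000, had means of 21.6-fold and 5.87-fold, so it was strong in both. The other MEF marks were raised there as well, at means of 4.27-fold H3K4me3 and 3.59-fold H3K27me3. In the highest bin they stood at 5.58-fold and 3.79-fold. Some strong H3K4me3 bins also carried H3K9me3 reads in the secondary library, as on chromosome 5 from 111660001 to 111665000 (H3K4me3 21.0-fold, secondary H3K9me3 12.6-fold, MEF H3K9me3 3.83-fold) and chromosome 9 from 21475001 to 21480000 (17.3-fold, 10.0-fold and 2.33-fold).

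The comparison of the H3K9me3 libraries asks how far the mark is placed alike in ordinary and in secondary fibroblasts. Called bins numbered 50912 in MEF and 46115 in secondary MEF, of which 25323 were the same bins, against 4744 for independent lists. This was 5.34 times independence. Pairs of different marks exceeded it: MEF H3K9me3 with MEF H3K27me3 at 5.71 times and secondary MEF H3K9me3 with MEF H3K4me3 at 5.95 times. The shared bins were 49.7% of the MEF bins and 54.9% of the secondary MEF bins. The shares fell to 34.4% and 29.1% with stricter thresholds of 3-fold and an adjusted value under 1e-06, and to 33.8% and 17.0% against the background of the other marks. What share repeat libraries of the same cells would reach was not measured, so an unshared bin need not be a site that differs. The secondary library was less tied to H3K27me3 and more to H3K4me3: 43.3% of its called bins were MEF H3K27me3 bins and 37.3% were MEF H3K4me3 bins, while in MEF these shares were 64.6% and 24.2%. H3K4me3 and H3K27me3 of secondary MEF were not analysed here, so both marks refer to MEF.

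The share of H3K9me3 library reads in secondary MEF relative to MEF fell along MEF H3K27me3 and rose over strong MEF H3K4me3. Outside chromosomes 12, X and Y and outside bins high in all 4 libraries, the ratio of read shares was 1.16 in bins with H3K27me3 under 0.5-fold, 0.879 (0.877 to 0.881) between 2-fold and 5-fold, and 0.706 (0.687 to 0.726) at 20-fold or more. Along H3K4me3 it was 1.01 in bins under 0.5-fold, lowest at 0.914 (0.912 to 0.915) between 0.5-fold and 1-fold, 1.43 (1.42 to 1.44) between 20-fold and 40-fold, and 1.61 (1.58 to 1.64) at 40-fold or more. Bins called one by one outside chromosomes 12, X and Y were set beside all 301212 bins compared there, and beside bins with like reads in the library that the call favours, both chosen after seeing the data. Of 1752 bins lower in secondary MEF, 73.4% were H3K27me3 bins, against 17.7% of all bins and 68.9% of bins with like MEF H3K9me3 reads. H3K4me3 bins made up 9.08% of them, against 9.65% and 28.0%. Of 1445 bins higher in secondary MEF, 48.9% were H3K4me3 bins, against 9.65% of all bins and 50.7% of bins with like secondary MEF reads. H3K27me3 bins made up 14.6% of them, against 17.7% and 48.9%. The call itself favours bins with many reads in one library, and matching on those reads favours bins with few in the other, so neither reference is neutral. Over all chromosomes, bins of 40-fold H3K4me3 or more were raised in every library. There 56.2% were called for H3K27me3, at a median of 2.07-fold, 68.7% for MEF H3K9me3 and 98.4% for secondary MEF H3K9me3. No input library was used, so whether the reads over strong H3K4me3 are the mark or background was not tested. The cell source and the flow cell changed together between the H3K9me3 libraries, so they cannot be told apart.

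**Figure D2:**
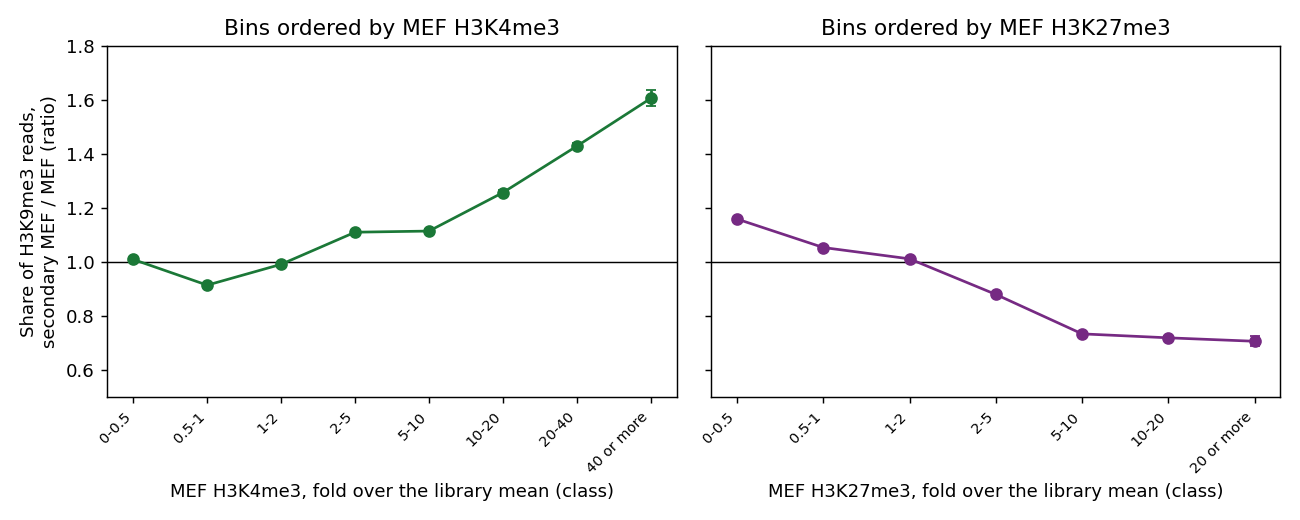
Ratio of the share of H3K9me3 reads in secondary MEF to that in MEF (y axis, bars 95% counting intervals, mostly within the points) for 5 kb bins sorted into classes of MEF H3K4me3 (left) or MEF H3K27me3 (right), without chromosomes 12, X and Y and without bins high in all 4 libraries. The ratio reached 1.61 at the top of the H3K4me3 scale and 0.706 at the top of the H3K27me3 scale.

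Chromosome 12 as a whole carried more reads in the secondary MEF H3K9me3 library. In bins called for neither H3K4me3 nor H3K27me3 in MEF, its share of reads was 1.47 times that in MEF (95% interval 1.46 to 1.47), while the 18 other autosomes had ratios of 0.987 ± 0.0456 (mean ± SD) between 0.894 and 1.08. All 12 of its 10 Mb windows, from 1.36 to 1.78, lay above the highest of 236 windows on the other autosomes, 1.26. Per bin, chromosome 12 stood at 1.36 times the autosomal mean in the secondary library, and at 0.917, 0.945 and 0.937 times in MEF H3K4me3, H3K27me3 and H3K9me3. The ratio of the secondary H3K9me3 library was 1.46 with MEF H3K27me3 as the reference and 1.49 with MEF H3K4me3. Of the bins of chromosome 12, 21.4% were called for H3K9me3 in secondary MEF and 8.86% in MEF. In the 1716 bins of chromosome 12 called in both libraries the ratio was lower, at 1.24, with 0.983 on the other autosomes. Chromosome X had a lower share in secondary MEF, at a ratio of 0.711 (0.705 to 0.716), and chromosome Y a higher one, at 1.62 (1.52 to 1.73), from 1602 reads in MEF and 2386 in secondary MEF. With MEF H3K4me3 and H3K27me3 as references, the X ratio was 0.793 and 0.589 and the Y ratio 2.18 and 2.74. Over the 26 bins of chromosome X called in both H3K9me3 libraries the ratio was instead 1.64. It was 1.11 without the 5 of them with the most reads and 0.947 without the 10 with the most. The ratio thus fell with few bins left out but stayed above that of the chromosome. A call in the secondary library, where the chromosome was low, also favours bins with many reads there.

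**Figure D3:**
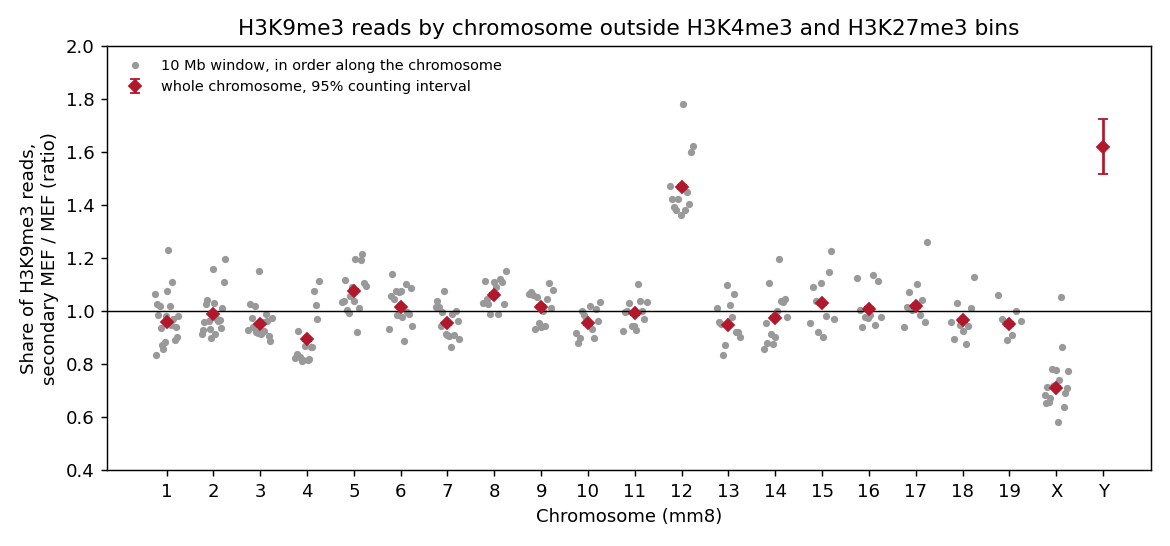
Ratio of the share of H3K9me3 reads in secondary MEF to that in MEF (y axis) for each chromosome of mm8 (x axis), in 5 kb bins called for neither H3K4me3 nor H3K27me3 in MEF. Diamonds are whole chromosomes with 95% counting intervals and grey points are 10 Mb windows in order; chromosome 12 stood at 1.47, X at 0.711 and Y at 1.62, and the other autosomes between 0.894 and 1.08.

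Of 321554 bins with at least 20 reads in the H3K9me3 libraries together, 2427 were at least 2-fold higher and 1853 at least 2-fold lower in secondary MEF, with the preset interval of the ratio excluding 1. Random reassignment of the pooled reads, drawn 20 times, gave at most 115 higher and 116 lower. Chromosome 12 held 972 of the higher bins and 1 of the lower ones. Chromosome 4 held 49 of the higher bins and 290 of the lower ones, or 15.7% of all lower bins with 5.74% of the compared bins. Without chromosomes 12, X and Y the counts were 1445 higher and 1752 lower, so with scaling by total reads the lower bins were then the more numerous. With each chromosome scaled to its own reads they were 1721 higher and 1513 lower over all chromosomes. Under that scaling chromosome 12 had 97 higher and 87 lower bins, and chromosome 4 had 143 and 107.

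Outside chromosome 12, the gain over the longest stretch was on chromosome 9 from 123770001 to 123790000, where distinct read positions numbered 379 in secondary MEF and 92 in MEF, a ratio of 4.61 (3.16 to 6.90). H3K4me3 had 456 distinct positions there in MEF and H3K27me3 89. The 8 longest stretches were all on chromosome 12, which was higher as a whole, and are not counted as regional gains. The longest, 40 kb from 105765001 to 105805000, had a ratio of 2.65 (2.01 to 3.52), of which the level of the whole chromosome is a part. Losses were shorter, at 15 kb or less, and 7 of the 10 longest lay over 486 to 747 distinct H3K27me3 positions. Chromosome 7 from 37895001 to 37910000 had 66 positions in secondary MEF and 248 in MEF, a ratio of 0.298 (0.183 to 0.465). Chromosome 8 from 123760001 to 123775000, inside the long H3K27me3 domain, had 83 and 239, a ratio of 0.388 (0.249 to 0.588). Chromosome 3 from 34850001 to 34865000 had 62 and 198, a ratio of 0.350 (0.210 to 0.561), over 576 H3K27me3 positions. These regions were ranked by length on one read per position, a ranking chosen after seeing the data. They were joined from bins that had each passed the rule on the same reads. Intervals that exclude 1 follow from that choice, and the ratios may be too far from 1.

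By the rule fixed beforehand, the 10 bins with the largest ratio in each direction were mostly small. The largest with reads in both libraries was chromosome 1 from 112175001 to 112180000, with 136 reads in secondary MEF and 4 in MEF, a 37.9-fold ratio (9.25 to 435), but the 136 reads came from 11 positions. Chromosome 8 from 62825001 to 62830000 followed with 125 and 4 reads, 34.9-fold (8.47 to 400), from 17 positions. With one read per position, 1 of the 10 higher bins still passed the rule. This was chromosome 8 from 126315001 to 126320000, where secondary MEF had 20 reads at 20 positions and none of the 3 MEF libraries had a read. Its ratio was 7.44 against a floor of 3 reads, and the preset interval of the counts started at 2.41. Of the 10 lower bins, 9 still passed, and 5 of the 10 were on chromosome X. That chromosome was lower as a whole: 100 of its bins were lower and 10 higher. Scaled to its own reads, it had 14 lower and 26 higher. The first of the 10 lower bins, chromosome X from 68245001 to 68250000, had 22 reads in MEF and 0 in secondary MEF. It was 6.57-fold lower against a floor of 3 reads, and the preset interval of the counts started at 2.17-fold.

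Across bins, MEF H3K9me3 correlated with MEF H3K27me3 at least as highly as with H3K9me3 of secondary MEF. Pearson's r of log2(RPM + 0.1) over the 494868 bins, which are not independent replicates, was 0.848 with H3K27me3 and 0.830 with secondary MEF H3K9me3, and Spearman's rho was 0.868 and 0.845. H3K27me3 and secondary MEF H3K9me3 had an r of 0.766, and H3K4me3 correlated with the other libraries at 0.707 to 0.729. Over the 419379 bins called for neither H3K4me3 nor H3K27me3 in MEF, MEF H3K9me3 correlated with H3K27me3 at 0.812. With secondary MEF H3K9me3 the value over these bins was 0.7997. Both correlations thus stayed high without the called bins, so they do not by themselves show marks placed together in called regions. A random split of the reads into equal parts gave 0.787 within the MEF H3K9me3 library, 0.826 within the deeper H3K27me3 library and 0.753 within the secondary one. It gave 0.842 within the H3K4me3 library. Each part holds fewer reads than its library, so these values are not a ceiling for the correlations above. H3K27me3 had a higher split value than secondary MEF H3K9me3. The small difference between 0.848 and 0.830 is not adjusted for depth or for the range of the signal. Given the remaining libraries, the partial correlation of MEF H3K9me3 was 0.548 with H3K27me3 and 0.461 with secondary MEF H3K9me3.

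A small set of positions was high in every library, and some of them still followed a mark. At 5-fold or more in all 4 libraries there were 81 bins in 61 regions, with 0.275% to 0.430% of a library's reads. Chromosome 17 from 39450001 to 39455000 reached 143-fold for H3K4me3, 445-fold for H3K27me3, 330-fold for MEF H3K9me3 and 419-fold for secondary MEF H3K9me3. Chromosome 2 from 98465001 to 98470000 reached 63.5-fold, 80.5-fold, 221-fold and 166-fold in the same order. The bin on chromosome 17 was the highest of each library.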

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

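Reads outside the main measurement were present in every library. Reads with 2 locations made up 2.26% of MEF H3K4me3 reads (95% interval 2.26 to 2.27), 2.70% of MEF H3K27me3 reads (2.69 to 2.71), 3.33% of MEF H3K9me3 reads (3.31 to 3.34) and 3.42% of secondary MEF H3K9me3 reads (3.40 to 3.43). Both H3K9me3 libraries thus had the larger shares. On chromosome Y they made up 38.9%, 43.5%, 44.9% and 45.1% of the listed positions in the same order.

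Reads with 1 location on the mitochondrial chromosome numbered 409 for MEF H3K4me3, 789 for MEF H3K27me3, 242 for MEF H3K9me3 and 393 for secondary MEF H3K9me3. Both kinds of reads exceed the 3 reads that a count of 0 allows. No control library was used here, so whether these reads are signal or background was not tested, nor was any explanation.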

How the results depend on the processing

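Of 88 alternatives of the main results, 49 left the value within its counting interval, or a count within 1.5 times. Another 39 moved it further and 0 were scored as reversed. A count or a share could not be scored as reversed, only a correlation or a chromosome ratio. The balance of higher to lower H3K9me3 bins was not scored. Higher bins made up 56.7% of the differing bins, and 45.2% without chromosomes 12, X and Y. Alternatives that added two-location reads, left out chromosomes 12, X and Y or bins high in all 4 libraries, scaled chromosomes apart, or took shared bins against the other marks were chosen after seeing the data, as were all alternatives of the overlaps of H3K27me3 with other MEF marks and of the chromosome ratios.

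Called bins, in the order H3K4me3, H3K27me3, MEF H3K9me3 and secondary MEF H3K9me3, numbered 19483, 28322, 25876 and 24432 at 10 kb, where each bin is wider by construction. Against the background of the other marks they numbered 18848, 26345, 4879 and 9662. With the stricter thresholds H3K27me3 had 23786, MEF H3K9me3 9276 and secondary MEF H3K9me3 10955. Bins with H3K4me3 and H3K27me3 numbered 6514 at 10 kb and 4051 with the stricter thresholds, and those with H3K9me3 and H3K27me3 18016 and 6896.

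The shared part of the MEF and of the secondary MEF H3K9me3 bins was 54.3% and 57.5% at 10 kb, 46.8% and 57.1% with one read per position, and 69.4% and 71.6% when a neighbouring bin counted. It was 34.4% and 29.1% with the stricter thresholds, 50.6% and 51.9% with MEF thinned to equal depth, 33.8% and 17.0% against the other marks, and 48.3% and 57.1% without chromosomes 12, X and Y.

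The correlation of MEF H3K9me3 with secondary MEF was 0.946 at 50 kb, 0.842 with a pseudocount of 1 and 0.727 in bins of at least 20 reads. With H3K27me3 these were 0.954, 0.856 and 0.774, and 0.847 without chromosomes 12, X and Y. Under those 3 alternatives the correlation with H3K27me3 stayed the higher one.

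Bins higher in secondary MEF numbered 1445 without chromosomes 12, X and Y, against 1752 lower. With each chromosome scaled to its own reads they numbered 1721 and 1513. With median-ratio scaling, a shift of -0.02 in log2, they numbered 2709 and 1587. The chromosome X ratio was 0.721 with two-location reads and 0.735 over all bins. Apart from bin width, the cause was not tested.

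Promoter and gene-list alternatives were not run and have no values. No paired analysis was possible because each group has 1 library. In simulated bins at the depth of the H3K9me3 libraries, a 2-fold change was recovered in 14% to 19% and a 5-fold change in 87.5% to 89.5%. The rule asks for an observed ratio of at least 2, and how much of the loss is due to depth was not tested.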

Other observations

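All tests of an explanation below were chosen after the result was seen.

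A few bins had reads in one kind of fibroblast only. In 9 bins the 3 MEF libraries had no read and secondary MEF had at least 10 at distinct positions, and 7 of them were on chromosome 8, including 4 between 15435001 and 15480000. In 18 bins secondary MEF had no read and the MEF libraries together had at least 30, and 9 of them were on chromosome X. That chromosome was lower as a whole in the secondary library, at a ratio of 0.711, so these bins are not counted as local losses. How many bins of either kind counting error alone would give was not tested.

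H3K9me3 and H3K27me3 were both strong in a few MEF bins outside positions high in all 4 libraries. The strongest by the smaller fold was chromosome 17 from 6200001 to 6205000, with 10.9-fold H3K9me3 and 12.1-fold H3K27me3. Next came chromosome 11 from 33095001 to 33100000, with 10.7-fold and 21.2-fold. Secondary MEF H3K9me3 stood at 8.99-fold and 11.8-fold in these bins.

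Chromosome 12 was higher in the secondary MEF H3K9me3 library. In bins under 0.5-fold MEF H3K9me3 it still stood at 1.44 times the other autosomes, which argues against a gain at marked regions only. Against the other autosomes the whole chromosome stood at 1.49, and 15 classes of bins by mark level gave 1.43 to 1.51, so an extra copy in the secondary cells, which gives 1.5, may contribute. In bins called in both libraries the ratio was 1.24, where a uniform gain predicts 1.28 because weaker bins of chromosome 12 also pass the call, and windows reached 1.78. A gain of H3K9me3 along the whole chromosome stays open without an input library or another mark from these cells.

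Chromosome X was lower and chromosome Y higher in the secondary MEF H3K9me3 library. With one read per position the Y ratio was 1.62, which argues against repeated reads at few positions. If all secondary cells were male, the X ratio of 0.720 against autosomes predicts a Y ratio of 1.64, and the measured one was also 1.64 with a lower limit of 1.54, so a different mix of male and female cells may contribute. The match held for MEF H3K9me3 as the reference only: with MEF H3K4me3 1.32 was predicted and 2.22 measured, and with MEF H3K27me3 3.18 and 2.75, where the mark differs as well. The sex of the cells was not given in the labels used, and few reads on Y have a single location.

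MEF H3K9me3 followed MEF H3K27me3. Reads carried over from the H3K27me3 library would add 148097 shared positions at the 13.4% of reads needed, but 8068 were found beyond neighbouring offsets. A bias shared by the libraries of one flow cell stays open: H3K4me3 correlated with MEF H3K9me3 at r 0.719 and with secondary MEF H3K9me3 at 0.729, while Spearman's rho ran the other way, at 0.796 and 0.787, and the partial correlations of 0.129 and 0.304 go against it but are adjusted for H3K27me3 of the same flow cell. Recognition of H3K27me3 by the H3K9me3 antibody could also give the pattern: the secondary library stood at a median of 2.97-fold where MEF H3K27me3 was between 10-fold and 20-fold. H3K27me3 of secondary cells was not analysed here. Recognition by the antibody and a true overlap of the marks would both raise H3K9me3 reads along H3K27me3 of the same cells. These and a bias of the flow cell cannot be told apart here.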
